A study of Mus musculus with 2 samples.

How the data were processed

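DNase-seq marks accessible chromatin: nuclei are treated with DNase I, an enzyme that cuts DNA mainly where no nucleosome covers it, and the cut ends are sequenced. The 2 samples are hippocampus tissue, given in the labels as a layer of the hippocampus, of female B6CASTF1/J mice, first-generation hybrids of the B6 and CAST strains, at 10 days of age. They form 1 group, with the replicate numbers 1 and 2 given in the labels. The labels give them separate biosample records and the same donor record, and mention 3 females without saying whether tissue was pooled, so part of the spread between the replicates may be technical. There is no second condition, so no test across conditions was possible and every SD rests on n = 2.

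Each sample came with a shorter and a longer peak list, a list of footprints and a list of bases with a low false discovery rate, all in mm10 coordinates and made from that sample's own filtered alignments, per the file headers and the notes deposited with the files. The aligner, the peak and footprint callers and their versions are not given in the sources used here. The authors' signal value of each peak, in the deposited peak lists, is a whole multiple of 1 step per library, 0.00620 in replicate 1 and 0.00359 in replicate 2. The scaling is not stated, so signal was used only to describe, rank and filter peaks within a replicate and to correlate shared peaks. The deposited false discovery rate (FDR), a p-value corrected for multiple tests, is listed for runs of bases and stays under 0.05, and it covered 34.1 Mb in replicate 1 and 57.4 Mb in replicate 2. The deposited footprints carry the p-value threshold 0.01 on every line, so only their positions were used. Total reads are not given in the sources used here. A deeper library gives more peaks and footprints, so each count between replicates can reflect depth.

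The comparisons, tests, gene lists, consensus sequences and named genes were chosen before the data were examined, except where stated. A narrower and a wider peak list per sample had been foreseen, but the lists differ in stringency and not in width. Every peak of the shorter lists held a base with FDR under 0.001, and every peak of the longer lists one under 0.05, so the shorter, stricter list was taken as the main one after the files were seen and before any result was computed. Coordinates are 1-based. Genes, exons and transcript starts came from GENCODE release M21, transcript starts and exons from its basic set, and sequence from the mm10 (GRCm38) reference.

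Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1, with 10 shuffles within chromosomes as background. Peaks within 1000 bp of a transcript start counted as promoter peaks for the location shares and all others as distal. Peaks outside exons but inside a gene's annotated span counted as intronic, and that span can reach beyond the transcripts of the basic set. For the gene lists, a promoter peak lay within 500 bp of any annotated start of the gene. The share of a list's genes with a promoter peak was set against 10000 random lists of protein-coding genes of the same size, drawn from the same decile of promoter CpG observed/expected ratio, with a permutation p counted on both sides. The mean number of distal peaks in the gene and 10 kb on each side was tested in the same way, matched on the decile of that window's length. The median difference in the rank of a gene's highest promoter signal, as a percentile among genes with a promoter peak in either replicate, was tested with lists matched on the decile of mean rank; genes with no peak in 1 replicate shared the lowest rank there. The smallest p these tests can give is 0.0002. Benjamini-Hochberg adjustment ran over all lists and replicates of a test, and a list was called only if both replicates passed 0.05 in the same direction. In the promoter and distal tests the Y list, whose outcome the sex label fixes, was included. Its low p-values lower the adjusted values of other lists. Genes are not independent replicates, so these p-values describe the 2 libraries. The random lists did not keep neighbouring genes together, so the p-values of lists from gene clusters treat neighbours as independent.

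The 26 lists covered pan-neuronal, glutamatergic neuron, forebrain and hippocampal transcription factor, hippocampal subfield, GABAergic interneuron, Cajal-Retzius, neural progenitor, activity-regulated, astrocyte, oligodendrocyte lineage, microglia, vascular, choroid plexus and ependyma, other brain region, Hox, erythroid, lymphoid, liver, muscle, epidermis, germline, olfactory receptor, housekeeping, imprinted, X inactivation and escape, and Y genes. From each list the text names up to 4 members with the highest mean rank of promoter signal among those with a promoter peak in both replicates, and up to 3 members with none in either, in alphabetical order. It also names the 5 protein-coding genes with the most distal peaks in both replicates, the 5 shared distal peaks of highest mean rank, and the loci Prox1, Zbtb20, Neurod1, Bdnf, Fos, Gad1, Gfap, Cx3cr1 and Alb. Other members are named where stated or beside a list's counts, and those were chosen after their values were seen. Some members that this rule selects are not reported here.

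Matches of 28 consensus sequences were counted on both strands in 150 bp at the centre of each distal peak and in windows of that width 1000 bp to each side that overlap no listed peak. The ratio of matches per kb has a 95% interval from 1000 bootstraps over peaks. An interval is given only with at least 5 matches on both sides, a minimum set after the results were seen, because intervals with 0 or 1 background matches were unbounded; the count of sequences above 1 was 11 with it. In footprints, matches whose centre lay inside a footprint were set against those in the rest of the same peaks. Footprints were shared at 50% reciprocal overlap.

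The alternatives were the longer list, the upper part of each list by signal (above its median), equal numbers of peaks, other overlaps, promoter distances and windows, lists without CpG matching, a GC-matched background, other window widths, and each replicate left out. Added after seeing the data were starts of the comprehensive annotation, matching on the number of starts, ranks among genes with a promoter peak in both replicates, footprints in shared peaks, and motifs in distal sites found in 1 replicate alone. The statistics were tested on simulated data over the 21938 protein-coding genes. With lists of 15 genes and no effect, an unadjusted p under 0.05 came for 4% of 200 lists in the promoter test, 3.5% in the distal test and 5.5% in the rank test. At the same unadjusted p in 1 simulated replicate, promoter lists raised to 95% or lowered to 20% were found in 81% and 91% of cases. Distal lists raised 3-fold were found in 100% and lists shifted by 10 rank points in 99%. The simulated distal counts were Poisson counts around a mean set by gene length, and any wider spread of the real counts was not simulated. The simulated rank differences were normal draws, without the shared lowest rank of genes that lack a peak in 1 replicate. These rates are therefore not those of the calls, which need an adjusted p in both replicates. A planted motif ratio of 3.52 over 20000 peaks came out as 3.51 (3.29 to 3.76), and a planted overlap of 69.3% as 69.3%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.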

Results

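DNase I hypersensitive sites were listed in 2 samples of hippocampus, numbered in the labels as biological replicates 1 and 2 of the same donor record, from female B6CASTF1/J mice aged 10 days. The stricter peak list of replicate 1 held 61480 peaks that covered 12.8 Mb, 0.483% of the genome. That of replicate 2 held 97360 peaks that covered 21.1 Mb, 0.797% of the genome. The longer lists held 105538 and 170265 peaks, and the median peak width was 200 bp in each of the 4 lists. The number of reads behind each library is not given in the sources used here, so the depth is unknown and no counting interval is given. Both samples belong to 1 group, so the comparisons that follow set the replicates side by side and set genes and sites within each replicate against matched controls. Unless the longer list is named, values come from the stricter list, and p-values describe these libraries.

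Accessible sites of replicate 1, among them the promoters of the neuronal genes Tubb3, Map2, Syp and Elavl3, were largely accessible in replicate 2 as well, whereas replicate 2 held many further sites. Of the replicate 1 peaks, 56569 (92.0%) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 56266 (57.8%) overlapped a replicate 1 peak, which made the mean share 74.9% ± 24.2 (SD, n = 2). Both shares come from 1 overlap divided by lists of different length. This SD therefore reflects list length and is not a spread of independent measurements. Positions shuffled within their chromosome overlapped at 1.65% and 1.05%. Over the 56569 pairs of overlapping peaks, the authors' log2 signal correlated between replicates with Pearson's r = 0.963 and Spearman's rho = 0.956, computed across peaks, which are not independent replicates. With the 61480 peaks of highest signal from each replicate, 81.3% and 80.6% were shared.

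The 41094 sites listed for replicate 2 only lay near genes' starts less often than the sites in both, which was not so for the sites listed for replicate 1 only. Among them 17.1% lay within 1000 bp of a transcript start and 41.6% in introns, against 37.4% and 30.5% of the shared replicate 2 peaks. Their median signal was 0.445, against 1.34 for the shared peaks. In replicate 1, 51.0% of these 41094 sites held a base with a deposited false discovery rate under 0.05, and 44.0% overlapped the longer list. Of the 4911 peaks listed for replicate 1 only, 40.6% lay within 1000 bp of a start, against 37.6% of the shared replicate 1 peaks. In replicate 2, 90.8% of them held such a base and 44.1% overlapped the longer list. More such bases were listed for replicate 2, 57.4 Mb against 34.1 Mb. These shares were not tested, since each rests on 1 library.

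Sites at transcript starts made up a large part of both hippocampus lists. On average 33.3% ± 6.39 (SD, n = 2) of peaks lay within 1000 bp of an annotated start, 37.9% in replicate 1 and 28.8% in replicate 2, against 4.57% of shuffled positions. Of the remaining peaks, those in exons made up 4.76% ± 0.939 of all peaks, those in introns 32.7% ± 3.50 and those between genes 29.2% ± 1.96. Of 21938 protein-coding genes, 12835 (58.5%) had a peak within 500 bp of a start in replicate 1 and 13797 (62.9%) in replicate 2. A promoter peak was present in both replicates for 12796 genes and in neither for 8102.

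Promoters of excitatory neurons' genes were open in both replicates more often than promoters of like CpG content, and promoters of genes of other brain regions, of the Hox clusters, of germ cells and of olfactory receptors were open less often. Of 14 glutamatergic neuron genes, 13 had a promoter peak in replicate 1 and 14 in replicate 2. Their mean share was 96.4% ± 5.05 (SD, n = 2), against 67.3% for random lists matched on CpG content (permutation p = 0.0042 and 0.0012, adjusted 0.0146 and 0.00480). The members with the highest signal ranks were Gria2, a subunit of AMPA glutamate receptors, Neurod2, a transcription factor of excitatory neurons, Nrgn, a calmodulin-binding protein of the postsynapse, and Grin2b, a subunit of NMDA receptors. Slc17a7, the vesicular glutamate transporter, had its promoter peak in replicate 2 only. The call was lost when the promoter window was narrowed to 100 bp, with a permutation adjusted p of 0.0585 in replicate 1, while the mean difference from random lists was 31.1 points, against 29.2 at 500 bp.

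Genes that mark other brain regions had a promoter peak in 2 of 15 cases in replicate 1 and 8 of 15 in replicate 2, a mean of 33.3% ± 28.3 against 79.4% for matched lists (permutation p = 0.0002, the smallest they can give, and 0.0016; adjusted 0.000945 and 0.00594). Pitx3, a transcription factor of midbrain dopamine neurons, was among those open in both. Barhl1, Foxa2 and Gabra6, the last a receptor subunit of cerebellar granule cells, had no promoter peak in either replicate. Random lists not matched on CpG content ended this call, with a permutation adjusted p of 0.709 in replicate 2. Hox genes, which pattern the hindbrain, spinal cord and trunk, had a promoter peak in 4 of 39 cases in replicate 1 and 6 of 39 in replicate 2, a mean of 12.8% ± 3.63 against 84.3%. The members open in both were Hoxa10, Hoxb5, Hoxc5 and Hoxc10. Of 10 germline genes, Dazl, an RNA-binding protein of germ cells, alone had a promoter peak in each replicate (10% against 80.5%), and Ddx4, Hormad1 and Mael had none. Of 1135 olfactory receptor genes, 8 and 14 had one, a mean of 0.969% ± 0.374 against 7.39%, with Olfr317, Olfr557, Olfr536 and Olfr658 ranking highest. For the Hox, germline and olfactory receptor lists the permutation p was 0.0002 in each replicate, the smallest they can give, with an adjusted value of 0.000945. The random lists did not keep neighbouring genes together, so for clustered genes such as the Hox genes neighbours were treated as independent.

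Inhibitory neuron genes and Cajal-Retzius genes had fewer promoter peaks in replicate 1 than promoters of like CpG content, and in replicate 2 they missed the threshold; the difference between the replicates in these shares was not tested. With only the upper part of each list by signal, both lists were called lower in both replicates, with highest permutation adjusted p of 0.000867 and 0.00809. Without CpG matching neither passed in both replicates, and the mean differences went from -27.8 to -4.43 points and from -38.8 to -4.78 points (highest permutation adjusted p of 0.257 and 0.837). Of 16 GABAergic interneuron genes, 5 had a promoter peak in replicate 1 (31.2%, against 81.3% for matched lists, permutation p = 0.0002, adjusted 0.000945) and 13 in replicate 2 (81.2% against 86.9%, permutation p = 0.640, adjusted 0.792). Open in both were Calb2 and Pvalb, calcium-binding proteins of interneuron classes, Gad1, which makes GABA from glutamate, and Erbb4, a neuregulin receptor. Lhx6, Slc32a1 and Sst, which encode a transcription factor, the vesicular GABA transporter and somatostatin, had none in either. The 8 found in replicate 2 only, chosen for naming after their values were seen, were Gad2, Dlx1, Dlx2, Dlx5, Dlx6, Vip, Cck and Nxph1. Their peaks were weak, with a median signal rank in replicate 2 at percentile 6.60. Cajal-Retzius cells, early-born neurons of the marginal zone, had a promoter peak at 3 of 8 genes in replicate 1 (37.5% against 93.5%, permutation p = 0.0004, adjusted 0.00173) and 6 of 8 in replicate 2 (75% against 96.7%, permutation p = 0.0514, adjusted 0.135). Ebf2, Ndnf and Cacna2d2 were open in both, and Lhx1 and Trp73 in neither. With the same number of peaks from each replicate, the counts were 5 and 9 for interneurons and 3 and 6 for Cajal-Retzius cells.

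**Figure D1:**
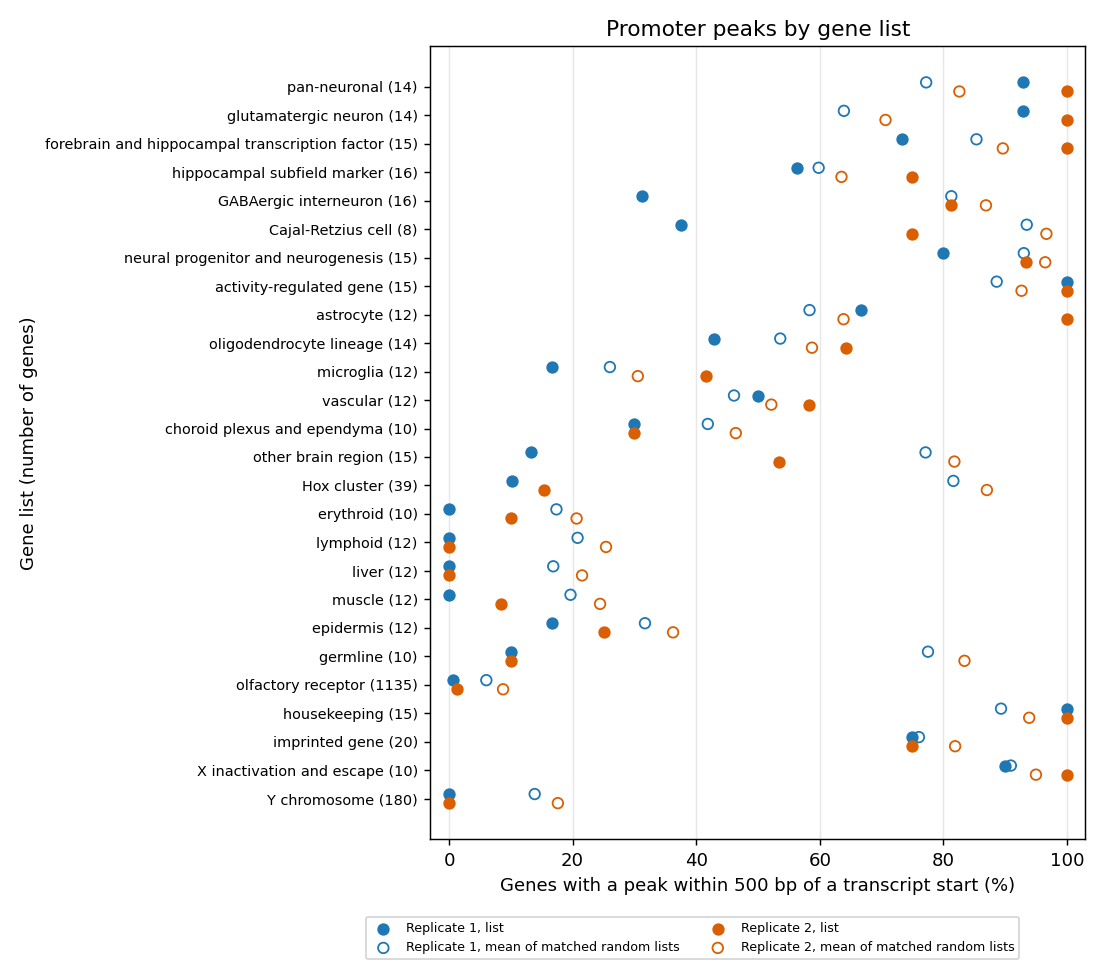
Share of each gene list's members with a peak within 500 bp of a transcript start, in percent, for replicate 1 (blue) and replicate 2 (orange); filled points are the lists and open points the means of 10000 random lists matched on promoter CpG content. The glutamatergic neuron list lies above its random lists in both replicates, at 92.9% and 100%, and the interneuron list lies at 31.2% in replicate 1 and 81.2% in replicate 2.

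Glial and vascular genes gave no call in both replicates with the stricter lists, and with the longer lists astrocyte genes were called higher in both (100%, a difference of 33.5 points, highest permutation adjusted p of 0.0111). All 12 astrocyte genes had a promoter peak in replicate 2 (100% against 63.8%, permutation p = 0.0002, adjusted 0.000945), and 8 of 12 in replicate 1 (66.7% against 58.3%, permutation p = 0.686, adjusted 0.829), among them Glul, the glutamine synthetase, Sox9, Aldoc and the glutamate transporter Slc1a2. Oligodendrocyte lineage genes had one in 6 and 9 of 14 cases (permutation adjusted p = 0.644 and 0.941). The progenitor receptor Pdgfra and the transcription factors Olig1, Olig2 and Myrf were open in both replicates, as were the myelin genes Mbp and Cnp, while the myelin genes Mag, Mobp and Mog were open in neither. Microglia genes had one in 2 and 5 of 12 cases (adjusted 0.759 and 0.661 by permutation), with Sall1 among those in both, and the complement genes C1qa and C1qb and the chemokine receptor Cx3cr1 in neither. Vascular genes had one in 6 and 7 of 12 cases (permutation adjusted p = 1 and 0.942), with Pdgfrb, Kdr, Slco1c1 and Kcnj8 open in both and the endothelial genes Cdh5, Cldn5 and Pecam1 in neither. Choroid plexus and ependyma genes had one in 3 of 10 cases in each replicate (permutation adjusted p = 0.661 and 0.381), namely Rsph1 and Foxj1, genes of motile cilia, and Kl, while Ccdc153, Clic6 and Folr1 had none.

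The other neural lists did not pass the threshold against promoters of like CpG content. Pan-neuronal genes had a promoter peak in 13 and 14 of 14 cases (92.9% against 77.2% and 100% against 82.6%, permutation adjusted p = 0.325 and 0.124). Without CpG matching, pan-neuronal and activity-regulated genes were called higher in both replicates, by 35.7 and 39.2 points (highest permutation adjusted p of 0.0233 and 0.00547). Forebrain and hippocampal transcription factors had one in 11 and 15 of 15 (permutation adjusted p = 0.395 and 0.313), with the mineralocorticoid receptor gene Nr3c2 and the developmental regulators Lhx2, Emx2 and Nfix ranking highest. Hippocampal subfield markers had one in 9 and 12 of 16 (permutation adjusted p = 0.987 and 0.335). Pcp4, Wfs1, a marker of CA1 pyramidal cells, Bok and C1ql2, a marker of dentate granule cells, were open in both, and Dcn, Iyd and Lct in neither. Neural progenitor genes had one in 12 and 14 of 15 (permutation adjusted p = 0.335 and 0.942), with Top2a, Sox4, Sox11 and Pax6 ranking highest and Eomes, a factor of intermediate progenitors, in neither. All 15 activity-regulated genes, induced by neuronal firing, had one in both replicates (100% against 90.6%, permutation adjusted p = 0.395 and 0.687), with the immediate early genes Jun and Egr1 and with Homer1 and Dusp1 ranking highest.

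Tissue genes from outside the brain mostly lacked a promoter peak, and so did many random promoters of like CpG content. Without CpG matching, erythroid, lymphoid, liver, muscle and epidermis genes were called lower in both replicates, by 39.8 points for epidermis to 60.6 for liver, and housekeeping genes higher by 39.4 points (highest permutation adjusted p of 0.0288 for epidermis and 0.00572 for housekeeping genes). None of 12 lymphoid genes, Cd3d and Cd3e among them, had one, against 20.8% and 25.4% for matched lists (permutation p = 0.0430 and 0.0104, adjusted 0.124 and 0.0338), so the list passed in replicate 2 alone. None of 12 liver genes, Alb, Ahsg and Apoa1 among them, had one (permutation adjusted p = 0.335 and 0.185). Erythroid genes had one in 0 and 1 of 10 (permutation adjusted p = 0.135 and 0.751), and Alas2, Epor and Gata1 had none. Muscle genes had one in 0 and 1 of 12 (permutation adjusted p = 0.180 and 0.395), and Acta1, Ckm and Myf5 had none. Epidermis genes had one in 2 and 3 of 12 (permutation adjusted p = 0.384 and 0.661), Krt10 and Grhl3 in both, and Dsg3, Ivl and Krt1 in neither. Housekeeping genes, led by Rplp0, Ppia, Polr2a and Ywhaz, had one in all 15 cases (permutation adjusted p = 0.532 and 0.889). Imprinted genes had one in 15 of 20 in each replicate (permutation adjusted p = 1 and 0.682), led by Kcnq1ot1, Peg13, Peg3 and Gnas, with Dlk1, Grb10 and H19 in neither. Adjusted values are Benjamini-Hochberg values over 26 lists in 2 replicates, and a list was called only if both replicates passed 0.05 in the same direction.

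Away from promoters, olfactory receptor genes held fewer accessible sites than other genes of like length, and genes of forebrain transcription factors held the most of the 26 lists. Olfactory receptor genes held a mean of 0.0943 distal peaks per gene in replicate 1 and 0.126 in replicate 2, against 0.764 and 1.52 for matched lists (permutation p = 0.0002, the smallest they can give, adjusted 0.00260 in each). Forebrain and hippocampal transcription factor genes held 7.47 and 20.1, against 2.49 and 4.65 (permutation p = 0.0070 and 0.0056, adjusted 0.0520 and 0.0485), so the list passed in replicate 2 and missed the threshold in replicate 1. With 50 kb on each side of the gene in place of 10 kb, it passed in both replicates, with a highest permutation adjusted p of 0.0461. Its counts in replicates 1 and 2 were 17 and 77 at Zbtb20, 31 and 67 at Nfib, 27 and 36 at Nfix, and 7 and 18 at Emx2. Prox1 held 2 and 3, Etv1 0 and 1 and Pou3f1 0 and 0, so a few members carry much of the list's mean. Activity-regulated genes held 2.6 and 4.4, against 0.930 and 1.75 (permutation p = 0.0024 and 0.0094, adjusted 0.0250 and 0.0578), and passed in replicate 1 alone. With only the upper part of each list by signal, these lists and the neural progenitor list passed in both replicates, with highest permutation adjusted p of 0.0312, 0.00650 and 0.00347. With distal meaning over 5000 bp from a start, none of these 3 lists passed in both: the mean difference from random lists was 7.04 for forebrain transcription factors, 0.105 for activity-regulated genes and 0.503 for neural progenitor genes, with highest permutation adjusted p of 0.0611, 1 and 0.585. The Y list, with 0 distal peaks, is left out here, since the sex label fixes its outcome. Its p-values still entered the adjustment, which lowers the adjusted values of other lists. The passes of the forebrain list near the threshold, at permutation adjusted p of 0.0485 and 0.0461, rest on that adjustment. They cannot be separated from the fixed Y outcome. None of the remaining lists passed in either replicate. The lowest permutation adjusted p among them was 0.0578, for glutamatergic neuron genes in replicate 2, which held a mean of 12 distal peaks against 4.37.

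The 5 protein-coding genes with the most distal peaks in both replicates were long as annotated. Their counts take in every distal peak in the annotated span and 10 kb on each side, so these peaks need not belong to the named gene. Gm20388 (chromosome 8, 119910841 to 124345722) spans 4435 kb and held 176 and 312. Fgfr2 (chromosome 7, 130162451 to 133123350) spans 2961 kb as annotated and held 75 and 129. Tenm2, a synaptic adhesion protein, spans 1229 kb and held 36 and 65. Auts2 spans 1106 kb and held 34 and 42, and Camta1, a calmodulin-binding transcription activator, spans 945 kb and held 32 and 45.

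The loci chosen for a closer account ranged from 0 peaks at Alb to 88 at Zbtb20. Zbtb20, a transcription factor of hippocampal pyramidal neurons (chromosome 16, 42875881 to 43642602), held 23 peaks in replicate 1 and 88 in replicate 2 within the gene and 10 kb on each side. Prox1, a transcription factor of dentate granule cells (chromosome 1, 190118035 to 190170714), held 4 in each. Neurod1 held 3 and 4, Bdnf, a neurotrophin, 7 and 11, and Fos, an immediate early gene, 5 and 7. The highest peak at Fos in both replicates was intergenic, on chromosome 12 from 85486121 to 85486240, 12291 bp from the nearest Fos start. Gad1 (chromosome 2, 70553072 to 70602014) held 4 and 13, and its highest peak in both began at position 70558241, inside the annotated gene span and upstream of every transcript start of the basic annotation, 3711 bp from the nearest in replicate 1. Gfap, the astrocyte filament gene, held 4 and 7, and the highest in each lay 83 and 93 bp from a start of Ccdc103. Cx3cr1 (chromosome 9, 119901616 to 120069879 as annotated) held 10 and 31 without a promoter peak. Of these, 7 and 21 were distal, and the others lay within 1000 bp of a transcript start. The highest in both was nearest to a start of Gm49427, so peaks in this span need not belong to Cx3cr1. Alb, the serum albumin gene of the liver, held none in either replicate.

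**Figure D2:**
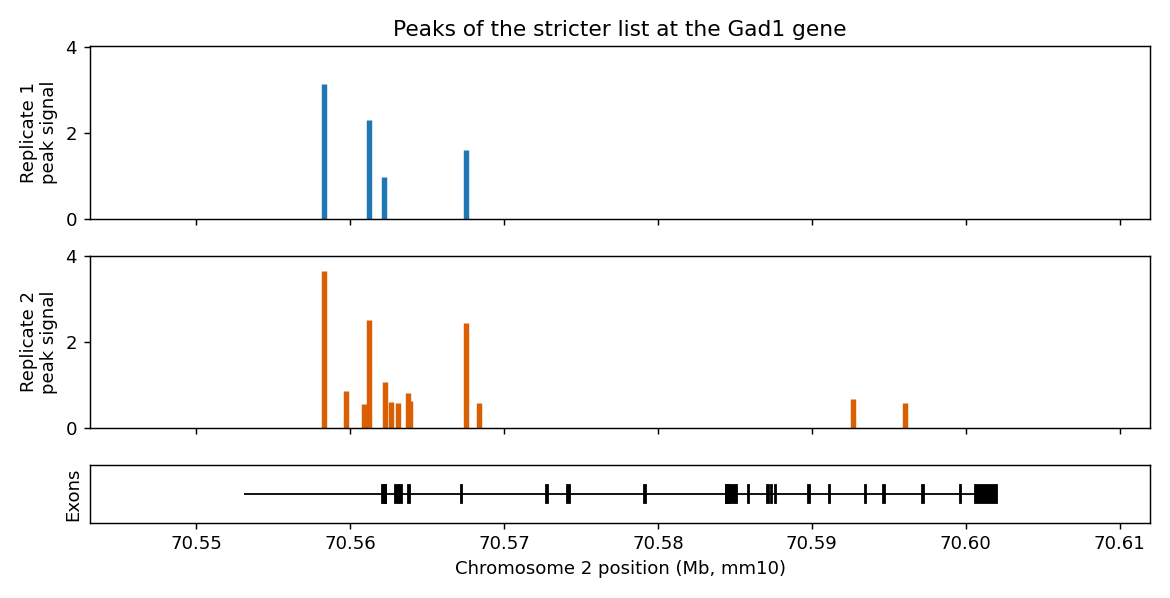
Peaks of the stricter list at the Gad1 gene and 10 kb on each side; the height of each bar is the authors' signal (scaling not given), the upper panels are replicates 1 and 2, and the lower panel shows the annotated span with exons of the basic annotation as boxes against the position on chromosome 2 in Mb. Replicate 1 has 4 peaks and replicate 2 has 13, and the highest begins at the same position in both, upstream of the exons drawn.

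The 5 shared distal peaks with the highest signal lay outside the listed neural genes. The first, on chromosome 15 from 99735661 to 99735920, lies in an exon of Cers5, 10173 bp from the start of Cox14, with a signal of 31.03 in replicate 1 and 28.1 in replicate 2. The second, on chromosome 9 from 123461901 to 123462100, lies in an exon of Lars2. The third (chromosome 3, 5860361 to 5860530) and the fourth (chromosome 6, 49236421 to 49236620) are intergenic, and the fifth (chromosome 13, 112578161 to 112578320) lies in an intron of Il31ra. For the second to the fifth, between 62.9% and 100% of their 31-base words occur elsewhere in the genome, and for the first 0%.

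No gene list passed the threshold in the rank test between the replicates, although the interneuron list held more promoter peaks in replicate 2. This test hardly registers peaks gained in replicate 2. Genes without a replicate 1 peak shared the rank 3.62 there, and protein-coding promoters found in replicate 2 only had a median rank of 5.62 in replicate 2. Random lists matched on mean rank can hold such genes too. The absence of a call therefore does not show that the lists kept their place. The median difference in the rank of promoter signal, replicate 2 minus replicate 1, was highest for oligodendrocyte lineage genes, at 6.15 percentile points over 9 ranked genes (permutation p = 0.0040, adjusted 0.0800). Cspg4, Nkx2-2 and Gpr17, which had no replicate 1 peak, entered it with the shared lowest rank of 3.62, and among genes with a promoter peak in both replicates the value was 1.93, below 2.33 for Hox and 2.14 for pan-neuronal genes. It was 3.19 for forebrain and hippocampal transcription factors over 15 genes (permutation p = 0.0524, adjusted 0.349) and 2.98 for interneuron genes over 13 (permutation p = 0.0476, adjusted 0.349). Of these 13, 8 entered with that lowest rank, and among interneuron genes with a promoter peak in both replicates the value was 0.0508. Neural progenitor genes had the lowest value among the neural lists, at -2.15 over 14 genes (permutation p = 0.210, adjusted 0.719). By this permutation test 0 of 20 lists with at least 3 ranked genes passed, and 2 had an unadjusted p under 0.05. Ranks were taken in lists of different lengths, so a difference in rank shows no change in accessibility, and the test compares 2 libraries, not conditions.

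Distal sites present in both replicates carried the consensus sites of CTCF, RFX, EGR and NeuroD-type factors more densely than their flanks, and those of GATA, T-box and SOX factors less densely. Over 34174 shared distal peaks, CTCF, the insulator protein, had 4562 matches against 30 in flanking windows, a density ratio of 279 (95% bootstrap interval over peaks 203 to 438). Over all distal peaks of replicate 2, without replicate 1, the ratio was 157 (124 to 210). RFX sites, bound by winged-helix factors, had a ratio of 39.4 (21.7 to 115) and EGR sites, bound by activity-induced zinc finger factors, 8.85 (5.90 to 14.2). The NeuroD-type E-box, bound by basic helix-loop-helix factors of neurons, had a ratio of 2.86 (2.71 to 3.02), the CAGCTG E-box 2.43 (2.34 to 2.53) and the cyclic AMP response element 4.30 (3.06 to 6.42). NRF1 had 6.50, SP/KLF 5.06, GRHL 2.81, NFY 1.19 and AP-1 1.17, each with an interval above 1. Without replicate 1 the GRHL ratio was 1.54 with an interval of 0.986 to 2.45, so its call ended. Below 1 with their whole interval against flanks were the GATA site at 0.359, the T-box site at 0.473, the Olig-type E-box at 0.560, the LHX-type homeobox site at 0.583, the FOX site at 0.757 and the SOX site at 0.763. In windows of 300 bp the calls of SOX, at 0.887 (0.778 to 1.01), and of NFY, at 1.04 (0.994 to 1.08), ended. Of the 28 sequences, 11 lay above, 6 below and 7 on neither side, and 4 had fewer than 5 matches on one side. Those 4 include the full NFI site, with 47 matches against 3, and the REST site, with 32 against 1.

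Several of these ratios differed when the flanks were replaced by windows of the same GC content elsewhere on the chromosome, over 35259 peaks. Against these windows, MEF2 went from 0.946 to 3.65 (2.41 to 6.24), LHX-type homeobox from 0.583 to 1.94 (1.73 to 2.17), FOX from 0.757 to 1.27 (1.09 to 1.46) and NFY from 1.19 to 0.852 (0.800 to 0.903). GRHL, a factor of epithelia used as a background sequence, fell to 1.04 (0.587 to 1.78). EGR had a ratio of 2.41, SP/KLF 1.61, the cyclic AMP response element 2.31, RFX 22.5, CTCF 154 and the NeuroD-type E-box 2.54, all with intervals above 1. HNF4, a factor of liver, had an interval across 1 with both backgrounds. In distal sites found in replicate 2 alone, CTCF had a ratio of 38.6 over 30362 peaks and the NeuroD-type E-box 2.64. Sequences were read from the reference genome, so sites that differ on the CAST chromosomes were not counted.

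Footprints, short stretches protected from cleavage inside accessible sites, carried CTCF, NRF1, SP/KLF and neuronal E-box sequences in both replicates. Replicate 1 had 263187 footprints with a median width of 10 bp and replicate 2 had 451336 with a median width of 9 bp. Of these, 64.6% and 58.2% lay inside peaks, and 40.9% and 33.8% within 1000 bp of a transcript start. At 50% reciprocal overlap, 107351 footprints were shared, 40.8% of those of replicate 1 and 23.8% of those of replicate 2, a mean of 32.3% ± 12.02 (SD, n = 2). Both shares divide the same overlap by lists of different length, so this SD reflects list length. Inside footprints, against the rest of the same peaks, CTCF sites were denser by ratios of 136 and 142 in replicates 1 and 2, NRF1 by 42.9 and 74.5, SP/KLF by 9.67 and 11.3, the cyclic AMP response element by 9.44 and 9.63, RFX by 7.43 and 9.06, EGR by 5.44 and 6.14 and the NeuroD-type E-box by 2.74 and 2.21. REST, a repressor of neuronal genes, had ratios of 13.2 and 25.5. AP-1 sites were less dense inside footprints, by ratios of 0.495 and 0.429, FOX sites by 0.314 and 0.274 and LHX-type homeobox sites by 0.413 and 0.459. In both replicates 13 of 28 sequences lay above 1 and 9 below with their whole bootstrap interval. Footprint calls rise with depth and can follow the sequence preference of DNase I, and neither was corrected for.

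**Figure D3:**
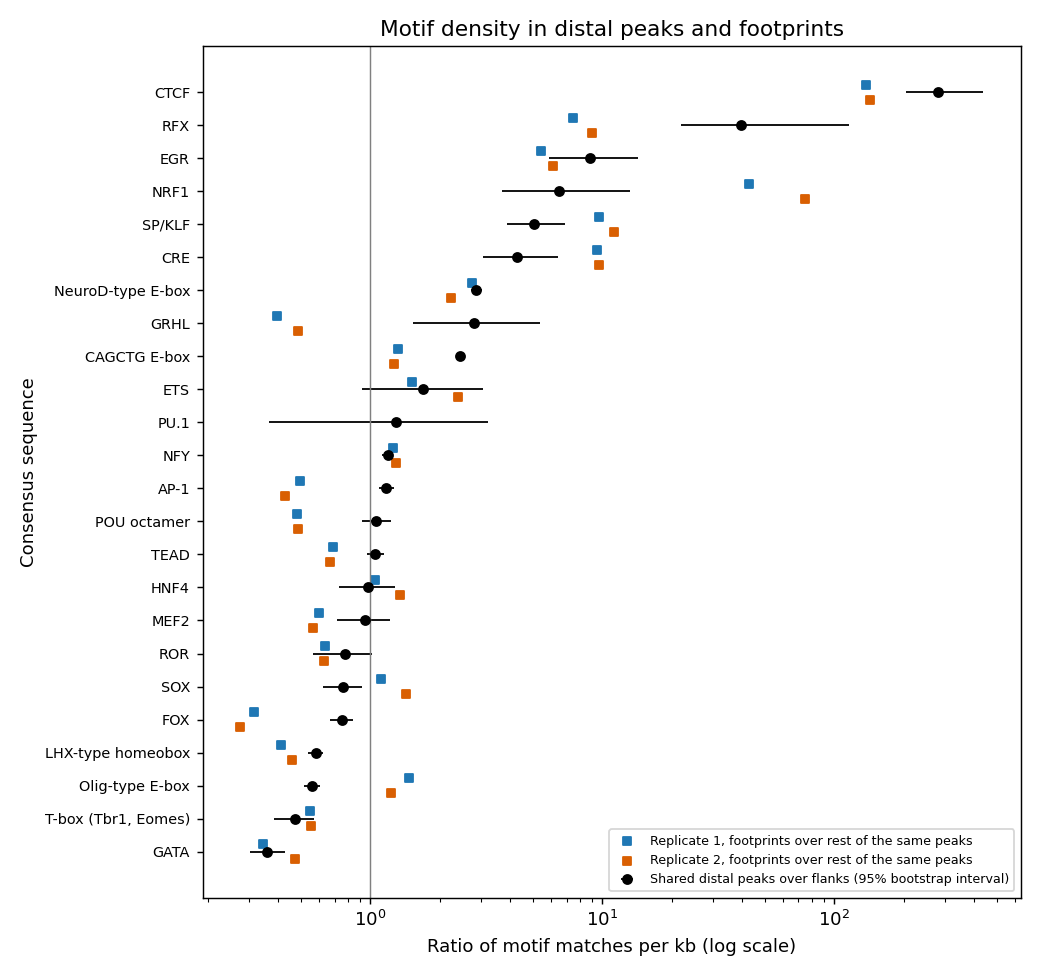
Ratio of consensus matches per kb, on a log scale, for the sequences with at least 5 matches on both sides; black points with 95% bootstrap intervals compare 34174 shared distal peaks with their flanks, and squares compare footprints with the rest of the same peaks in replicate 1 (blue) and replicate 2 (orange), drawn where both sides held enough matches. CTCF stands highest in each, at 279 in distal peaks and at 136 and 142 in footprints, and AP-1 lies above 1 in distal peaks (1.17) and below 1 in footprints (0.495 and 0.429).

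Footprints with a listed sequence in both replicates stood at several of the chosen loci. Upstream of the Gad1 starts of the basic annotation and inside the gene's annotated span, footprints held a CTCF match on the minus strand of chromosome 2 from 70558328 to 70558339, which reads GCCCCCTGCTGG on the plus strand, and another from 70561199 to 70561210, GCCCTCTGGTGG. In the intergenic peak near Fos, footprints held an SP/KLF match on the minus strand of chromosome 12 from 85486170 to 85486179, GCCCCGCCCC on the plus strand, and an EGR match from 85486191 to 85486199, CGCCCCCGC. Just outside the outer end of the annotated Gfap span, upstream of the starts of the basic annotation, one held a CTCF match on chromosome 11 from 102900988 to 102900999, CCACTAGATGGC. In Zbtb20, one held a CTCF match on the minus strand of chromosome 16 from 43435156 to 43435167, GCCATCTAGTGG on the plus strand.

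Both samples are labelled female, and none of the 180 protein-coding genes of chromosome Y outside the pseudoautosomal region had a promoter peak. Autosomes held 24.97 peaks per Mb in replicate 1 and 39.7 in replicate 2, chromosome X 10.0 and 13.6, and chromosome Y 0.227 and 0.318. The Y density was 0.00855 ± 0.000768 (SD, n = 2) of the autosomal density and the X density 0.372 ± 0.0419. Among the named Y genes, Ddx3y and Eif2s3y, which have copies on X, and 1700040F15Rik had no promoter peak. The 20 and 28 Y peaks stood mainly, in 15 and 17 cases, between positions 90717601 and 90744820. This stretch ends just before the pseudoautosomal region, the part shared with X. Of 10 genes of X inactivation and escape, 9 and 10 had a promoter peak (permutation adjusted p = 1 in each replicate), led by Kdm6a, Ftx, Kdm5c and Ddx3x. Xist, the RNA that coats the inactive X, had a promoter signal of 0.986 and 0.925. The share of protein-coding genes with a promoter peak was 59.6% and 64.2% on autosomes and 44.7% and 47.3% on X.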

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

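Motifs in distal sites found in 1 replicate alone, starts of the comprehensive annotation, matching on the number of transcript starts, ranks of genes with a promoter peak in both replicates and footprints in shared peaks were tests chosen only after the results were seen. Of 37 alternative values of the main results, 29 kept within their limits and 8 moved. The limit was the SD over the 2 replicates for a mean. For the sharing of peaks and of footprints, that SD reflects the different list lengths. For a count the limit was a fixed fold range, whichever lists or sequences were counted. With 1 replicate left out, a promoter or distal list had to pass in the other alone, so these counts could not fall. The 29 therefore do not measure how robust the results are. The mean promoter share of peaks was 26.2% at 500 bp, 41.2% at the longer of the alternative distances, 24.9% with the longer lists and 44.2% with the upper part of each list by signal; the distance widens or narrows the share by construction, and for the lists the cause was not tested. Without 1 replicate it ranged from 28.8% to 37.9%. Promoter lists past the threshold, with the Y list, whose outcome the sex label fixes, counted among them, numbered 13 without CpG matching, 5 of the 6 among them, and 8 and 8 without either replicate. Distal lists numbered 5 with the upper part by signal, and 3 and 3 without either replicate. Sequences above 1 in distal peaks numbered 12 and 12 without either replicate, and 3 in the 2730 peaks found in replicate 1 alone, where 13 of 28 had fewer than 5 matches on a side. Footprint sharing was 46.6% at an overlap of at least 1 bp, a looser criterion by construction. Inside peaks present in both replicates it was 43.6%, with 47.4% in replicate 1 and 39.7% in replicate 2.

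Some single results changed direction, and the cause was not tested. Among those below, the Hox distal list, MEF2, ROR and POU had no call in the main setting, so they gained one rather than reversed one. Hox genes held 0.371 fewer distal peaks than random lists when distal meant over 5000 bp (a difference of -0.371). Transcript starts of a Hox cluster lie close together, so little of a cluster is over 5000 bp from every start. Matching on window length did not allow for this, so the lower count need not reflect accessibility. With a GC-matched background, MEF2 had a ratio of 3.65, LHX-type homeobox 1.94, FOX 1.27 and NFY 0.852. In distal peaks found in replicate 1 alone, ROR had 3.28 (1.15 to 12.6, on 11 and 6 matches), and in those found in replicate 2 alone POU had 0.852. NFY with 0.999 and FOX with 1.03 in the former, and NFY with 0.996 and GRHL with 0.845 in the latter, had intervals that included 1, so these lost their call. Without a change of direction, T-box with 0.825, SOX with 0.807 and AP-1 with 1.28 lost theirs in the former. In the latter, T-box with 0.922 and SOX with 0.937 lost theirs. Over single lists and sequences, 191 of 208 promoter, 123 of 130 distal, 129 of 155 motif and 36 of 36 rank difference alternatives kept their side of the threshold. For lists and sequences not called in either setting the direction was not compared, and some changed sign. Replicate agreement, footprint sharing and rank differences need both replicates, so none could be computed without one. Depth is unknown for both libraries, which limits every count set between them.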

Other observations

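The tests of more interneurons in replicate 2 and the 2 tests of male tissue were chosen only after the result was seen. No biological explanation beyond these was tested, since the design holds 1 group.

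Of all protein-coding genes, 1001 had a promoter peak in replicate 2 only, and some list members among them are named here after their values were seen. Among forebrain transcription factors they included Zbtb20, Pou3f1 and Nfia, among astrocyte genes Gfap, Aqp4, Aldh1l1 and Fgfr3, and among genes of other brain regions En1, En2, Barhl2, Atoh1, Slc6a3 and Tlx3. At Zbtb20 and Gfap this holds for the starts of the basic annotation, since both replicates had a peak at the outer end of the Gfap span, and the highest Zbtb20 peak in both lay at the outer end of the annotated gene span, nearest to a start of 4932412D23Rik. No member of the 26 lists had a promoter peak in replicate 1 only. With the same number of peaks from each replicate, the counts in replicates 1 and 2 were 11 and 15 for forebrain transcription factors, 8 and 11 for astrocyte genes and 2 and 4 for other brain regions. The Olig-type E-box, bound by basic helix-loop-helix factors, was less dense in shared distal peaks than in their flanks, with a ratio of 0.560, and denser in footprints than in the rest of the same peaks, with ratios of 1.46 and 1.23. The full NFI site had ratios of 57.5 and 71.004 in footprints, on 4 and 5 matches in the rest of the peaks.

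Of 16 interneuron genes, 8 had a promoter peak in replicate 2 only. Fewer peaks called in replicate 1, a depth effect, may account for part of this: with the same number of top peaks the gap fell to 4, between the bounds set for and against that explanation, and 4 of the 8 promoters stood in the longer list of replicate 1, against 667 of the 1001 protein-coding promoters found in replicate 2 only. More interneurons in replicate 2 could also account for it. The ratio of distal peaks at these genes, 3.14 on summed counts per gene of 22 and 69, lay at percentile 94.4 of random lists. Their median was 1.8, so the ratio decides neither way. The windows of Dlx1 and Dlx2, and of Dlx5 and Dlx6, overlap, so a peak can count more than once. The random lists did not keep neighbouring genes together. The 8 promoters had weak peaks, with a median signal rank in replicate 2 at percentile 6.60, against 5.62 for the 1001. Depth and the share of interneurons cannot be told apart with 1 library each and unknown read totals.

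The 5 highest shared distal peaks may hold reads shared with other copies of the same sequence. The median share of their 31-base words with a second copy in the genome was 75.4%, at percentile 100 of medians of 5 random shared distal peaks. Those medians had a median of 0%. Over the 300 single random peaks they were drawn from, the mean share was 1.58%. The peak in the Cers5 exon, with 0%, is the exception. Whether reads with several positions were kept is not given in the sources used here.

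Peaks on chromosome Y in samples labelled female may come from reads shared with sequence on another chromosome. The mean share of their 31-base words with a copy on another chromosome was 38.9%, with 33.1% and 43.0% in replicates 1 and 2. The highest of 100 sets of random Y windows had 31.7%. Peaks of both replicates were pooled for this and most stood in 1 cluster, while the random windows were spread over the chromosome. The peaks are thus not independent, so this comparison cannot decide whether shared reads account for them. In replicates 1 and 2, 7 of 20 and 5 of 28 peaks held no such word. The 4 promoters of Ddx3y, Eif2s3y, Kdm5d and Uty, genes used in most male tissues, argue against male tissue as most of a sample, since 0 had a peak in the longer lists of either replicate. A small share of male tissue stays open: 0 peaks of the longer lists inside protein-coding Y genes lacked such a copy, but a share too small to give peaks would leave none, and the Y peaks without a copy are not accounted for. Most of the Y peaks, 15 of 20 and 17 of 28, stood in 1 cluster that ends just before the pseudoautosomal region. A sequence that differs between the strain and the reference there was not tested, nor was a link to that region.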
